A study of Homo sapiens with 4 samples.

How the data were processed

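RNA was sequenced from 4 samples of A549 cells, 2 treated with 100 nM dexamethasone and 2 with 0.02% ethanol for 3 h. Per the labels' protocols, total RNA was taken from column extracts with a DNase step, and libraries were made from mRNA with an automated kit. The deposited files hold raw counts, 1 file per library, with a transcript name, its length, the number of aligned reads and the number of unaligned reads. Per the submitters' processing notes, CASAVA, Bowtie, SAMtools and DESeq2 were used, with no version, role or order stated. The aligner settings, genome build, annotation release and strand setting are not given in the sources used here. Counts are listed over 119207 transcript sequences with GENCODE-style names. How many alignments of a read were kept is not given, and each count is taken here as a read. Reads shared by transcripts of a gene, by near-identical genes or by overlapping genes are placed by the aligner and not resolved. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

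Depth ranged from 9764159 to 11887526 reads aligned to named transcripts per library. The unnamed row of each file, which holds unaligned reads, made up 17.2% and 18.7% of all reads in dex replicates 1 and 2 and 18.5% and 17.2% in etoh replicates 1 and 2, and it was kept out of library sizes and tests. A gene at 0 in a library lies below a floor of 3 counts, which is between 0.252 and 0.307 CPM. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. No pair of libraries was a duplicate: the ratio of chi-square to degrees of freedom over genes was 3.97 within dex, 5.61 within etoh and 10.1 or more between groups.

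Transcripts were grouped by gene identifier into 34608 genes, 15346 of them with 1 transcript. The transcript with the largest total over the 4 libraries stood for its gene, and these transcripts held 53.1% and 53.7% of the aligned reads in dex and 54.6% and 54.0% in etoh. Library size was the total of all aligned reads. Gene positions, biotypes and 3' UTRs came from GENCODE 29 on GRCh38, in which 94.8% of the gene identifiers were found, and were used only for annotation.

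Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, normalization factors were by TMM, and dex was compared with etoh by the quasi-likelihood test with a prior count of 0.125 for fold changes, two-sided, with Benjamini-Hochberg adjustment over all 13799 tested genes. The threshold was an adjusted p of 0.05. Every adjusted p printed for a gene comes from this test unless another tool is named. The biological coefficient of variation was 8.41%. The SE of a log2 fold change was its absolute value divided by the square root of the quasi-likelihood F statistic. It was thus derived from the test and is approximate at low counts. For genes with at most 3 reads in a group, the ratio of summed counts per effective library size is given with an exact conditional binomial interval at the 95% level.

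Before the data were examined, 30 gene lists, the tests, the rule for named genes and the processing alternatives were fixed. The rule took the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a mean of at least 2 CPM and libraries that did not overlap between groups, leaving out clone-type and small RNA names. It added the 6 genes with the smallest p-values of each direction, up to 4 members with the smallest p-values from each list (or 2 abundant members where fewer than 2 passed), and NR3C1, FKBP5, TSC22D3, PER1, DUSP1, IL8 and IL6. This gave 116 genes, and 27 further genes were chosen after their values were seen, among them NFKBIA, RGS2, CSF1, LIF, SNAI2, JUN, JUNB, SCNN1A, NQO1, KLF15, ANXA1, CRY2, MKI67, HSPE1, SQSTM1, TXNRD1, ID2, VEGFA, LUCAT1, MIR503HG, PXN-AS1, SLC7A11-AS1, AREG, ZC3H12A, ZFP36L2 and PRRG3. Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, all in limma 3.58.1, with Benjamini-Hochberg adjustment over the 30 lists. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries, so it has little power here.

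The alternatives were DESeq2 size factors, upper-quartile factors and library totals in place of TMM, no count filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0 and limma-voom as tests, a robust dispersion fit, the replicate number as a block, an adjusted p of 0.01, the sum of all transcripts of a gene, removal of mitochondrially encoded genes and removal of each library in turn. Removal of transcripts with a run of at least 30 A or T was added after the data were seen. Where a group kept 1 library, that library was assumed to vary like the other group.

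The code was tested on simulated data drawn from the means, library sizes and edgeR dispersions of the 13799 genes in dex against etoh. The edgeR values below thus hold under its own model, with fewer changed genes than the 1300 called in the data. Recovery in the real comparison may differ. The 200 changed genes were picked from those with a mean above 2 CPM, so recovery of genes below that level was not measured. edgeR recovered 43.3% of 67 genes changed 1.5-fold, 86.6% of 67 changed 2-fold and all 66 changed 4-fold, with 6 false calls, or 3.77% of its calls. DESeq2 recovered 19.4%, 70.1% and 97.0% with 0 false calls, and limma-voom 41.8%, 85.1% and 100%. The 3' UTR and neighbour tests used 10000 random sets or permutations, with genes matched in classes of CPM and, for 3' UTRs, of length and AU content. In 40 simulations with no effect the neighbour test passed its range 1 time and the 3' UTR test 0 times, and in 40 with a planted effect both passed every time. A 3' UTR was found for 97.0% of lower and 96.4% of higher coding genes. Shared sequence was searched with BLAST 2.17.0, at 97% identity over at least 100 bases for named genes. No sequence was found for 838 tested genes, and the named genes ZFP36, NAV3, TP63, RP11-1002K11.1, SQSTM1 and HIST1H2BK are 6 of these, so shared sequence was not searched for them. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Some genes taken by the rule or chosen later are counted in the totals but not reported here. Transcript usage within genes was not analysed here, and binding data of the wider study were not used here.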

Results

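RNA was measured by sequencing in A549 cells, an established human lung adenocarcinoma line with features of alveolar type II epithelium. Cells received 100 nM dexamethasone, a synthetic glucocorticoid that activates the glucocorticoid receptor, or 0.02% ethanol as vehicle, for 3 h. Each group had 2 libraries, called dex and etoh here after the labels. The libraries held 9828448 and 11138944 reads aligned to named transcripts in the dex group, and 9764159 and 11887526 in the etoh group. A further 17.2% and 18.7% of the reads in the dex libraries, and 18.5% and 17.2% in the etoh libraries, were listed as unaligned. The series concerns where the glucocorticoid receptor binds the genome and how its direct sites relate to other transcription factors. The comparison of dex with etoh asks which transcripts differed in abundance after 3 h of hormone. All group values below are means ± SD over n = 2 libraries, in reads of the gene scaled to library size (CPM), and all log2 fold changes are dex against etoh with their standard error (SE).

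Transcripts changed in both directions after 3 h of dexamethasone. TFCP2L1, a transcription factor of epithelial cells, rose from 14.9 ± 1.22 to 228 ± 9.99 CPM, a log2 fold change of 3.94 (SE 0.13). FKBP5, a co-chaperone of the glucocorticoid receptor, rose from 6.73 ± 1.01 to 64.6 ± 1.75 CPM, and its log2 fold change was 3.25 (SE 0.15). EREG, an epidermal growth factor receptor ligand, went from 202 ± 6.08 to 29.5 ± 0.383 CPM, a log2 fold change of -2.78 (SE 0.12), and CYP24A1, the enzyme that inactivates vitamin D, from 1091 ± 0.866 to 164 ± 28.9 CPM. Of 13799 tested genes, 1300 (9.42%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 815 higher and 485 lower in dex. Among them 463 changed at least 2-fold, 330 higher and 133 lower, and 93 were higher and 25 lower by at least 4-fold. DESeq2 called 715 genes, 456 higher and 259 lower. The number of genes called was 848 without etoh replicate 1, with 304 lower, and lay between 921 and 1493 without each of the other libraries.

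**Figure D1:**
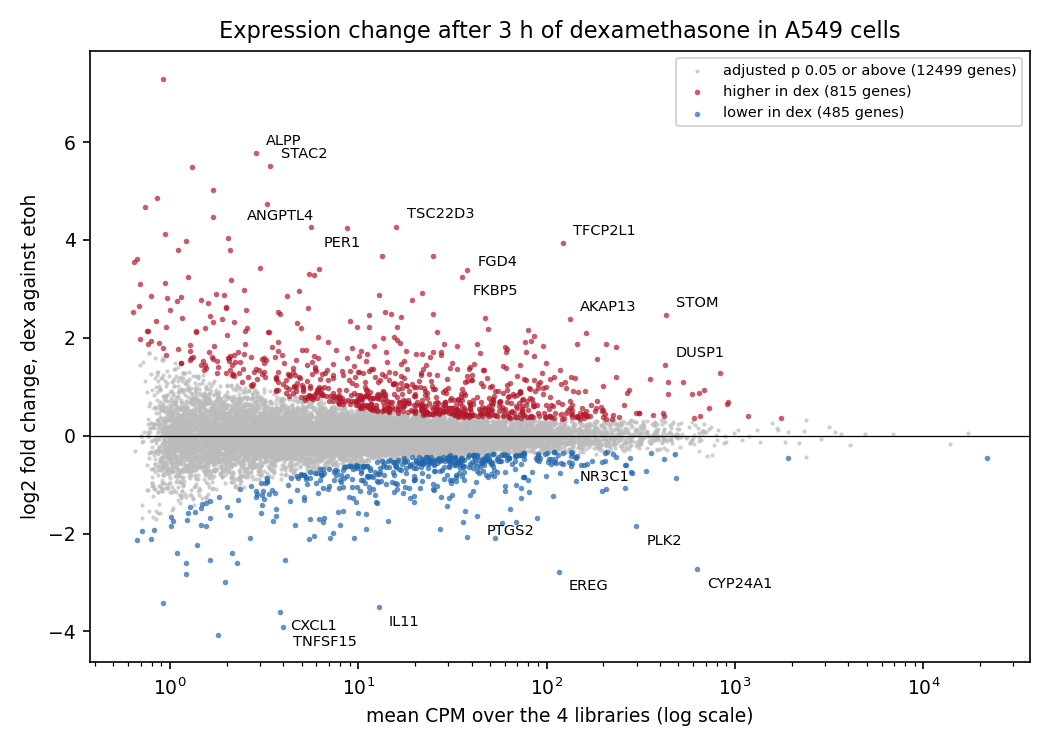
Each point is a gene, with its mean CPM over the 4 libraries on the horizontal log axis and its log2 fold change, dex against etoh, on the vertical axis. The 815 genes called higher are red, the 485 called lower blue and the others grey, and fitted values of genes with few or no vehicle reads, such as ALPP and STAC2, depend on the prior count.

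Besides TFCP2L1, the genes with the largest increases included several with few reads of the counted transcript in vehicle. TSC22D3, which encodes the leucine zipper protein GILZ, rose from 1.53 ± 0.292 to 30.2 ± 3.24 CPM (log2 fold change 4.27, SE 0.21). With all its transcripts summed, TSC22D3 had means of 7.65 CPM in etoh and 168 CPM in dex. PER1, a component of the circadian clock, rose from 1.95 ± 0.415 to 24.7 ± 1.48 CPM (3.68, SE 0.21). The secreted lipase inhibitor ANGPTL4 rose by 4.24 on the log2 scale (SE 0.28) and the lipid droplet protein CIDEC by 4.26 (SE 0.33). DNAJC15, a mitochondrial co-chaperone, rose by 4.74 (SE 0.47), RRAD, a small GTPase, by 3.79 (SE 0.48), and IRAK3, an inhibitor of Toll-like receptor signalling, by 4.04 (SE 0.53). Without etoh replicate 2, the log2 fold change was 5.30 for ANGPTL4 and 5.11 for IRAK3, and without etoh replicate 1 that of RRAD was 4.48. The placental alkaline phosphatase gene ALPP had 117 dex and 2 etoh reads, a ratio of 61.8 with a 95% counting interval of 16.7 to 516. STAC2 had 140 dex and 3 etoh reads, a ratio of 49.3 with an interval of 16.5 to 242, and its log2 fold change of 5.50 was 4.75 when all transcripts of the gene were summed. ALPP and IRAK3 each share a stretch of identical sequence with an overlapping gene model of the reference.

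Of the genes with the largest decreases, TNFSF15, a member of the tumour necrosis factor family, went from 7.50 ± 2.07 to 0.470 ± 0.224 CPM (log2 fold change -3.91, SE 0.38), and its log2 fold change was -4.53 without dex replicate 2. The chemokine CXCL1 went from 7.12 ± 0.592 to 0.567 ± 0.214 CPM (-3.59, SE 0.35). IL11, a cytokine of the IL6 family, went from 23.5 ± 0.419 to 2.09 ± 0.419 CPM (-3.50, SE 0.20). NAV3 fell by 2.60 on the log2 scale (SE 0.40), C6orf141 by 2.54 (SE 0.30) and TP63, a p53-related transcription factor, by 2.40 (SE 0.40). RND1, a small GTPase, fell by 2.11 (SE 0.26), and FST, which binds and blocks activins, by 2.09 (SE 0.34). TNFSF15 shares a stretch of near-identical sequence with other tested genes, so part of its reads cannot be assigned with certainty.

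Among the genes with the smallest p-values of each direction, STOM, a membrane scaffold protein, rose from 132 ± 23.6 to 728 ± 2.89 CPM (log2 fold change 2.46, SE 0.12, adjusted p = 1.2e-14 by edgeR). FGD4, an exchange factor for CDC42, rose by 3.39 (SE 0.15), the vasoconstrictor peptide gene EDN2 by 3.67 (SE 0.17) and AKAP13, an anchoring protein for protein kinase A, by 2.39 (SE 0.12). PLK2, a polo-like kinase, went from 467 ± 6.20 to 129 ± 7.04 CPM (-1.85, SE 0.11, adjusted p = 4.9e-13 by edgeR). NR5A2, a nuclear receptor of liver and pancreas, fell by 2.07 (SE 0.14), and the clone-named gene RP11-1002K11.1 by 2.09 (SE 0.14). AKAP13 overlaps antisense genes that were also counted, and its reads cannot be told apart from theirs because the strand setting is not given in the sources used here. In GRCh38, TFCP2L1 lies on chromosome 2 from 121216587 to 121285207, FKBP5 on chromosome 6 from 35573585 to 35728583 and PER1 on chromosome 17 from 8140472 to 8156506. EREG lies on chromosome 4 from 74365143 to 74388751, CYP24A1 on chromosome 20 from 54153449 to 54173973 and PLK2 on chromosome 5 from 58453982 to 58460260.

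**Figure D2:**
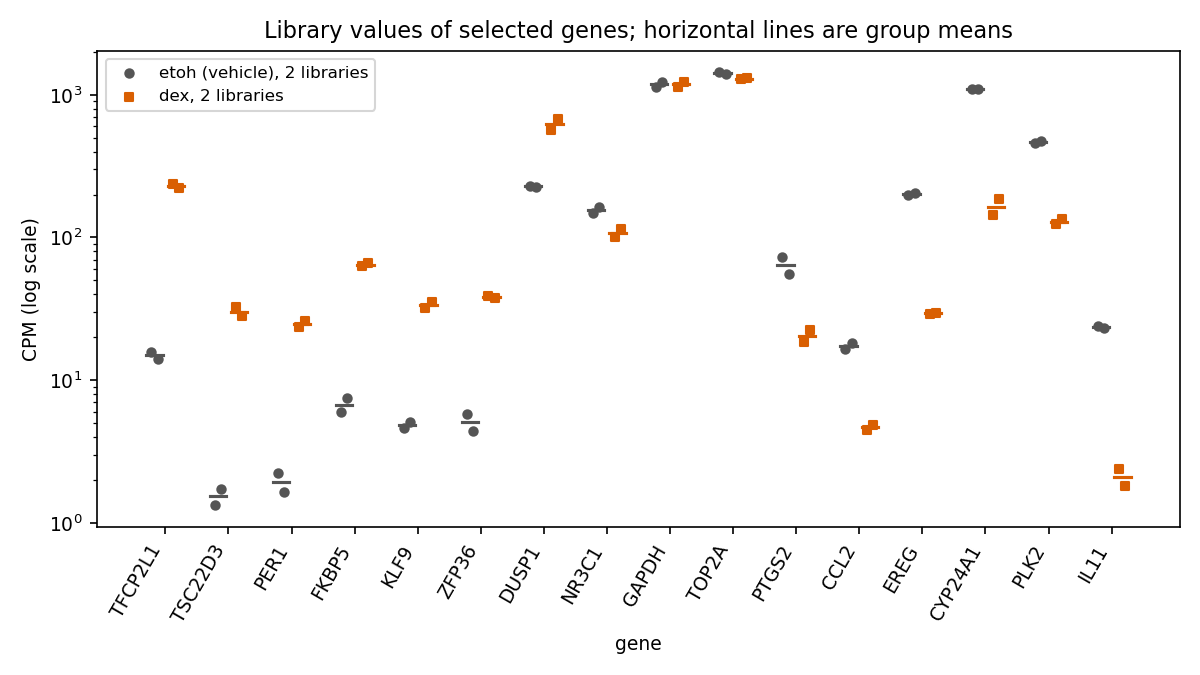
CPM of 16 genes on a log axis, with each library as a point, grey circles for etoh and orange squares for dex, and the group mean as a line. TFCP2L1 lies near 15 CPM in etoh and above 221 in both dex libraries, whereas GAPDH had means of 1181 in dex and 1183 in etoh.

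Of 35 tested genes on a list of known glucocorticoid-induced genes, 29 rose over all genes tested and 31 adjusted over the list alone. Camera, a test of a list against the other genes, put the list higher (adjusted p = 3.2e-129), with adjusted p = 0.17 with an estimated correlation. The form with an estimated correlation has little power with so few libraries, here and for every list below. KLF9, a Krüppel-like transcription factor, rose from 4.86 ± 0.385 to 33.5 ± 2.15 CPM (2.78, SE 0.16), and ZFP36, which binds AU-rich elements and speeds mRNA decay, from 5.09 ± 1.01 to 38.4 ± 1.01 CPM (2.93, SE 0.16). DUSP1, a phosphatase of MAP kinases, rose from 228 ± 2.86 to 623 ± 80.6 CPM (1.45, SE 0.11). NFKBIA, the inhibitor of NF-kB, rose by 1.88 (SE 0.13) and RGS2, which restrains G protein signalling, by 2.18 (SE 0.13). Among the 6 members that did not pass were ANXA1 at -0.18 (SE 0.10) and KLF15 at -0.27 (SE 0.19), and without etoh replicate 1 KLF15 passed at -0.67. NR3C1, which encodes the glucocorticoid receptor itself, went from 156 ± 10.5 to 108 ± 10.8 CPM (-0.53, SE 0.11, adjusted p = 0.0014 by edgeR).

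Of 23 tested NF-kB driven cytokine, chemokine and adhesion genes, 13 fell and 3 rose, and 14 and 3 adjusted over the list alone. Camera put the list lower (adjusted p = 1.0e-10), with adjusted p = 0.17 with an estimated correlation. PTGS2, the inducible cyclooxygenase, went from 64.5 ± 12.3 to 20.5 ± 2.73 CPM (-1.64, SE 0.14), and the monocyte chemokine CCL2 from 17.4 ± 1.13 to 4.66 ± 0.271 CPM (-1.90, SE 0.18). The growth factor CSF1 fell by 1.38 on the log2 scale (SE 0.18) and the cytokine LIF by 1.12 (SE 0.15). IL8, a neutrophil chemokine, had 4 dex and 75 etoh reads and fell by 4.06 (SE 0.52). BIRC3, an inhibitor of apoptosis and also a member of the glucocorticoid-induced list, rose from 34.3 ± 7.81 to 131 ± 1.55 CPM (1.94, SE 0.13). Without etoh replicate 1, 1 member of the list was higher instead of 3. IL6 was below the count filter and was not tested.

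Of 20 tested immediate-early and AP-1 genes, which respond first to growth signals, 6 rose and 8 fell (7 and 9 adjusted over the list alone), and camera did not call the list (adjusted p = 0.70). KLF4 rose by 1.58 (SE 0.20), KLF6 by 1.38 (SE 0.12) and JUNB by 1.02 (SE 0.14), whereas IER5 fell by 1.26 (SE 0.13) and JUN by 0.76 (SE 0.14). The number lower was 5 without dex replicate 1, without etoh replicate 2 and with DESeq2. Of 17 feedback inhibitors of MAP kinase signalling, 3 rose and 5 fell, the same numbers adjusted over the list alone, and camera did not call the list (adjusted p = 0.48). ERRFI1, an inhibitor of the epidermal growth factor receptor, rose from 88.5 ± 0.531 to 323 ± 2.92 CPM (1.87, SE 0.11). The phosphatase gene DUSP4 went from 136 ± 6.17 to 42.5 ± 1.23 CPM (-1.68, SE 0.12) and PHLDA1 fell by 1.22 (SE 0.13). PHLDA1 overlaps a counted antisense gene.

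Of 18 circadian clock genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone), with a camera adjusted p of 0.014 and an adjusted p = 0.28 with an estimated correlation. Besides PER1, the nuclear receptor gene NR1D2 rose by 1.49 (SE 0.11), the kinase gene CSNK1D by 0.60 (SE 0.12) and CRY2 by 1.13 (SE 0.22), and the repressor BHLHE40 fell by 0.83 (SE 0.11). Of 17 KLF and C/EBP transcription factors, which act in differentiation and metabolism, 6 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 2.4e-06, adjusted p = 0.24 with an estimated correlation). CEBPB rose by 1.22 (SE 0.12) and CEBPD by 1.66 (SE 0.19). Without etoh replicate 1, 2 members of the KLF and C/EBP list were lower.

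Of 19 genes of glucose handling, 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.022, adjusted p = 0.27 with an estimated correlation). The insulin receptor substrates went opposite ways, with IRS2 up by 1.83 (SE 0.11) and IRS1 at -0.82 (SE 0.13), and PDK4, which holds back pyruvate oxidation, rose by 1.71 (SE 0.12). The insulin receptor INSR rose by 0.89 (SE 0.17). Without dex replicate 1, etoh replicate 1 or etoh replicate 2, and with DESeq2, 1 member of the glucose list was lower. Of 20 genes of lipid storage and fatty acid metabolism, 4 rose, the same adjusted over the list alone (camera adjusted p = 3.4e-04, adjusted p = 0.24 with an estimated correlation). Besides ANGPTL4 and CIDEC these were the acyl-CoA synthetases ACSL1, up by 1.79 (SE 0.20), and ACSL3, up by 0.46 (SE 0.11). Of 20 genes of cholesterol synthesis and uptake, 2 fell, and 3 adjusted over the list alone, with camera adjusted p = 0.19. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, fell by 0.64 (SE 0.15). INSIG1 did not pass without dex replicate 1, at -0.55, without etoh replicate 2, at -0.54, or with DESeq2. DESeq2 called 0 cholesterol genes lower, and with all transcripts summed 2 were higher and 2 lower. Without dex replicate 1 or etoh replicate 1, 1 cholesterol gene was lower, and without etoh replicate 1, 1 was higher.

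Of 3 tested metallothioneins, small metal-binding proteins, 2 rose and all 3 adjusted over the list alone (camera adjusted p = 1.7e-10, adjusted p = 0.17 with an estimated correlation). MT2A rose by 1.68 on the log2 scale (SE 0.13) and MT1X by 2.00 (SE 0.17), and both are also members of the glucocorticoid-induced list. MT1X overlaps another counted gene, so the assignment of part of its reads is uncertain. Of 14 genes of epithelial sodium, chloride and water transport, 6 rose and 1 fell (8 and 2 adjusted over the list alone), with a camera adjusted p of 8.6e-09 and an adjusted p = 0.17 with an estimated correlation. The kinase SGK1, which raises sodium uptake, rose by 1.36 (SE 0.13), the sulfate transporter SLC26A2 by 0.85 (SE 0.10) and the epithelial sodium channel subunit SCNN1A by 1.61 (SE 0.34). Without dex replicate 2 or etoh replicate 2, 2 transport genes were lower.

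Of 17 epithelial junction and keratin genes, 6 rose and 3 fell (6 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.055). The keratin KRT8 rose from 338 ± 28.3 to 721 ± 127 CPM (1.09, SE 0.12), KRT7 by 0.68 (SE 0.11) and the desmosomal protein PKP2 by 1.53 (SE 0.19), and the tight junction protein CLDN1 fell by 0.84 (SE 0.11). KRT8 and KRT7 overlap other counted genes. Without etoh replicate 1, 1 junction gene was lower. Of 5 tested surfactant and alveolar genes, CAV1, the coat protein of caveolae, rose by 0.47 (SE 0.10) and the transcription factor ETV5 fell by 0.80 (SE 0.13), with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.97). Without dex replicate 2, or with all transcripts summed, 2 alveolar genes were higher. Of 28 TGF-beta responsive, mesenchymal and matrix genes, 8 rose and 2 fell (10 and 2 adjusted over the list alone), with a camera adjusted p of 0.0091 and an adjusted p = 0.30 with an estimated correlation. The matrix protein THBS1 rose by 1.10 (SE 0.10), the receptor TGFBR1 by 1.19 (SE 0.11) and the transcription factor SNAI2 by 2.85 (SE 0.31). The ligand TGFB2 fell by 1.55 (SE 0.13) and ID2, an inhibitor of helix-loop-helix factors, by 1.00 (SE 0.12).

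Of 18 YAP and SRF responsive genes, 5 rose and 3 fell (6 and 4 adjusted over the list alone), with a camera adjusted p of 0.022 and an adjusted p = 0.27 with an estimated correlation. CTGF, a matricellular growth factor, rose from 29.3 ± 0.228 to 131 ± 17.1 CPM (2.16, SE 0.12), ANKRD1, a muscle ankyrin repeat protein, by 1.39 (SE 0.14) and F3, tissue factor, by 1.60 (SE 0.23), and the vasoconstrictor gene EDN1 fell by 0.79 (SE 0.12). THBS1 and CTGF overlap other gene models, and the counted transcript of ANKRD1 holds a run of 30 A or T.

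None of 25 S and G2/M phase genes passed edgeR's test (0 called over all genes and 0 adjusted over the list alone), with 2 higher and 0 lower at an unadjusted p below 0.05, and DESeq2 and limma-voom called 0. With all transcripts of a gene summed, 1 was called higher. TOP2A, a topoisomerase of dividing cells, was at -0.13 (SE 0.10), the replication clamp PCNA at 0.03 (SE 0.11) and MKI67 at 0.17 (SE 0.11), and camera gave an adjusted p of 0.64. Of 17 G1 cyclins and cyclin-dependent kinase inhibitors, 6 rose and 1 fell (6 and 3 adjusted over the list alone), with a camera adjusted p of 0.00997 and an adjusted p = 0.27 with an estimated correlation. CDKN1A rose by 1.18 (SE 0.13), and the stress genes GADD45A and GADD45B by 1.70 (SE 0.15) and 1.29 (SE 0.16). CDKN1C had 48 dex and 3 etoh reads, a ratio of 16.9 with a 95% counting interval of 5.45 to 84.8. Its ratio was 9.33 without etoh replicate 1 and at least 7.57-fold higher without etoh replicate 2, against a floor of 3 counts over the group. The number of cell cycle control genes lower was 0 without dex replicate 1, without etoh replicate 2 and with DESeq2. It was 2 without dex replicate 2, with limma-voom, library totals, no count filter, a robust dispersion fit or summed transcripts.

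Of 19 regulators of apoptosis, 3 rose and 2 fell (6 and 2 adjusted over the list alone), and camera did not call the list (adjusted p = 0.054). MCL1, which protects cells from death, rose from 424 ± 21.4 to 765 ± 46.7 CPM (0.85, SE 0.10), and the death-promoting BCL2L11 fell by 0.56 (SE 0.13). BCL2A1 fell by 1.16 (SE 0.30). BCL2L11 did not pass without etoh replicate 1, at -0.44, and BCL2A1 did not without dex replicate 1, at -0.96, without etoh replicate 2, at -0.78, or with DESeq2. The number of apoptosis genes lower was then 1 in each of these leave-outs and with DESeq2.

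Of 22 antioxidant genes that respond to NRF2, a factor kept active in A549 cells by a KEAP1 mutation, 8 fell and 3 rose (8 and 5 adjusted over the list alone). Camera put the list lower (adjusted p = 0.0027), with adjusted p = 0.24 with an estimated correlation. The cystine transporter SLC7A11 fell by 0.85 on the log2 scale (SE 0.10), and GCLM, a subunit of the enzyme that starts glutathione synthesis, went from 352 ± 4.31 to 211 ± 10.9 CPM (-0.74, SE 0.10). HMOX1, heme oxygenase, fell by 0.74 (SE 0.12), the sulfiredoxin SRXN1 by 0.85 (SE 0.12) and TXNRD1, thioredoxin reductase, by 0.60 (SE 0.11), whereas the quinone reductase NQO1 was at 0.01 (SE 0.10). The number lower was 5 without dex replicate 1 and 5 without etoh replicate 2. The number higher was 0 without dex replicate 1, 1 without etoh replicate 1 and 5 without etoh replicate 2. SLC7A11, SRXN1 and NQO1 share sequence with overlapping counted genes.

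Of 19 hypoxia responsive genes, 5 rose (8 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 0.0091 and an adjusted p = 0.37 with an estimated correlation. NDRG1 rose by 1.73 (SE 0.19), the carbonic anhydrase CA9 by 0.99 (SE 0.15), DDIT4, an inhibitor of mTOR, by 0.79 (SE 0.11), the angiogenic factor VEGFA by 0.64 (SE 0.17) and the mitophagy receptor BNIP3 by 0.49 (SE 0.12). BNIP3 did not pass without dex replicate 1, at 0.35, and VEGFA did not without dex replicate 1, at 0.57, without etoh replicate 1, at 0.60, or with DESeq2. Of 19 mTOR inhibitors and autophagy genes, 5 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.24 with an estimated correlation). FOXO3 rose by 1.49 (SE 0.13) and FOXO1 by 1.22 (SE 0.18), both transcription factors that act in starvation, and the autophagy receptor SQSTM1 fell by 0.46 (SE 0.12). SQSTM1 did not pass without dex replicate 2, at -0.42, or without etoh replicate 2, at -0.40, and 1 autophagy gene was lower without any 1 of the 4 libraries and with DESeq2. FOXO3 shares near-identical sequence with another counted gene, and CA9, DDIT4 and VEGFA overlap counted antisense genes.

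Of 17 heat shock and chaperone genes, 4 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.0091, adjusted p = 0.27 with an estimated correlation). FKBP5 belongs to this list as well, and the co-chaperone BAG3 rose by 1.34 (SE 0.11), HSPB1 by 0.73 (SE 0.13) and DNAJB1 by 0.63 (SE 0.11), whereas the mitochondrial chaperonin HSPE1 fell by 0.72 (SE 0.15). HSPE1 overlaps HSPD1 and did not pass without etoh replicate 1, at -0.46. The number of heat shock genes lower was 0 without etoh replicate 1, and 1 without dex replicate 2 or etoh replicate 2 and with DESeq2. None of 18 unfolded protein response genes passed edgeR's test (0 over all genes and 0 adjusted over the list alone), with 0 higher and 1 lower at an unadjusted p below 0.05 and 0 called by DESeq2 and limma-voom, and 1 was called higher with all transcripts summed. The chaperones HSPA5 and HSP90B1 were at -0.02 (SE 0.10) and 0.06 (SE 0.10), with a camera adjusted p of 0.80.

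Of 16 interferon responsive genes, SOCS1, an inhibitor of cytokine signalling, was the 1 that rose, also adjusted over the list alone (camera adjusted p = 0.74). It had 30 dex and 1 etoh reads, a ratio of 31.7 with a 95% counting interval of 5.27 to 1293, and it was not tested without dex replicate 2. Its ratio was 17.5 without etoh replicate 1 and at least 4.73-fold higher without etoh replicate 2, against a floor of 3 counts over the group. Of 19 nuclear receptors and their coregulators, 4 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.64). The coactivator PPARGC1B rose by 1.35 (SE 0.14) and the retinoic acid receptor RARA by 0.96 (SE 0.22), and NR3C1 and the corepressor NRIP1, at -0.52 (SE 0.12), were lower. DESeq2 called 1 list member higher and 3 lower, and RARA was not among its calls. NRIP1 did not pass without etoh replicate 1, at -0.47, when 2 list members were higher and 2 lower. RARA and NRIP1 overlap counted antisense genes.

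**Figure D3:**
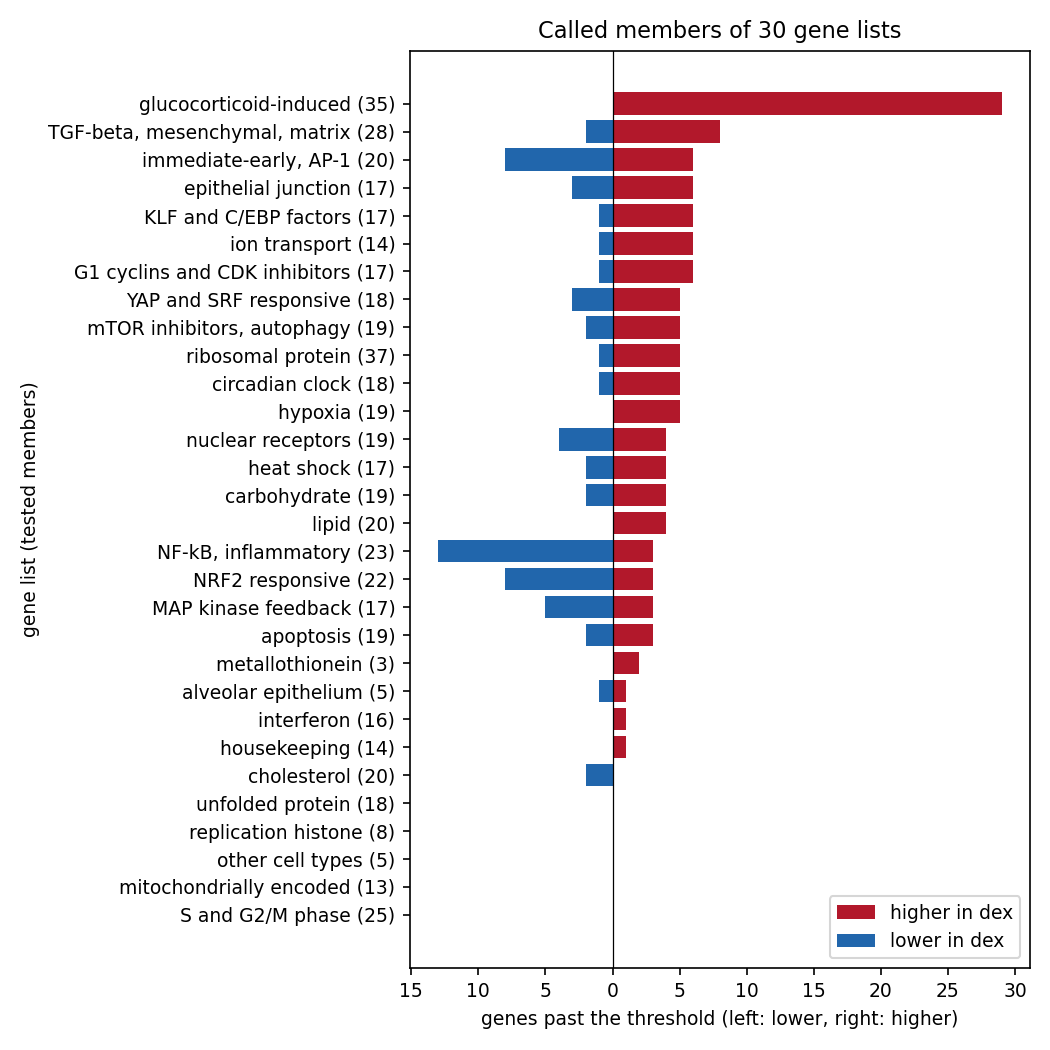
For each of 30 gene lists, with the number of tested members in brackets, bars to the right count members higher in dex and bars to the left members lower in dex, past the threshold over all tested genes. The glucocorticoid-induced list had 29 members higher and the NF-kB list 13 lower.

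Among markers of fibroblasts, endothelium and blood, 5 genes were tested and 0 passed edgeR's test over all genes or adjusted over the list alone, with 1 higher and 0 lower at an unadjusted p below 0.05 and 0 by DESeq2 and limma-voom (camera adjusted p = 0.97). COL1A1, a fibroblast collagen, was at 0.51 (SE 0.19, adjusted p = 0.096), and it passed at 0.68 without dex replicate 1, at 0.89 without etoh replicate 2 and at 0.56 with all transcripts summed. None of 13 mitochondrially encoded transcripts passed (0 over all genes and 0 adjusted over the list alone), with 1 higher and 1 lower at an unadjusted p below 0.05 and 0 by DESeq2 and limma-voom (camera adjusted p = 0.97). MT-CO1 was at 0.06 (SE 0.12), and the mitochondrial share of reads was 5.13% and 4.53% in dex and 4.39% and 5.15% in etoh. Without dex replicate 2, 1 mitochondrial transcript was called higher, and without etoh replicate 2, 2 were called higher and 1 lower. None of 8 replication-dependent histone genes passed (0 over all genes and 0 adjusted over the list alone), with 0 higher and 1 lower at an unadjusted p below 0.05 and 0 by DESeq2 and limma-voom (camera adjusted p = 0.69). HIST1H2BK was at 0.00 (SE 0.13).

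Of 37 ribosomal protein genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a camera adjusted p of 0.041 and an adjusted p = 0.64 with an estimated correlation. RPL19 rose by 0.66 (SE 0.14) and RPL3 by 0.53 (SE 0.14), and RPL27 fell by 0.45 (SE 0.12). Without dex replicate 1, RPL19 at 0.34, RPL3 at 0.21 and RPL27 at -0.44 did not pass, and neither did RPL3 at 0.41 and RPL27 at -0.35 without etoh replicate 1. RPL3 and RPL27 were not called by DESeq2, nor RPL3 with a robust dispersion fit. The number of ribosomal protein genes higher ran from 1 without dex replicate 1 and 2 without etoh replicate 1 to 8 without dex replicate 2 or etoh replicate 2, and was 2 with DESeq2 and 3 with a robust dispersion fit. Of 14 reference genes, ACTB rose by 0.36 (SE 0.11), the 1 call also adjusted over the list alone (camera adjusted p = 0.81), and GAPDH was at -0.00 (SE 0.10), with 1181 ± 64.6 CPM in dex and 1183 ± 75.8 CPM in etoh. The antisense gene RP5-940J5.9, which overlaps GAPDH and shares sequence with it, had 1617 ± 336 CPM in dex and 2221 ± 14.0 CPM in etoh. It was called lower (-0.46, SE 0.12, adjusted p = 0.0098 by edgeR), so the reads of this locus were not flat as a whole. ACTB did not pass without etoh replicate 1 at 0.24, or with library totals in place of normalization factors, at 0.33.

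Camera called 16 of the 30 lists with its preset correlation of 0.01 and 0 with an estimated correlation. With 4 libraries the second form has too few degrees of freedom for its lack of calls to be read. The NF-kB list had an estimated correlation of -0.0314, below the preset, yet its unadjusted camera p went from 6.9e-12 to 0.017. The lost call of that list thus does not show an effect of correlation between its genes. Among other called lists, the estimate was also below the preset for the lipid (-0.0341) and glucose (-0.0539) lists. It was above the preset for the ribosomal protein (0.157), glucocorticoid-induced (0.112) and hypoxia (0.105) lists. For lists above the preset, an effect of correlation cannot be told apart from the low power. The self-contained test fry, which asks whether a list moved on balance in 1 direction without setting it against other genes, called 17 lists, and its mixed form called 23. The list calls are not separate results, since members of the glucocorticoid-induced list also belong to other lists. Examples are MT2A and MT1X (metallothioneins), TSC22D3, SGK1 and SCNN1A (transport), ANGPTL4 and CIDEC (lipid), and IRS2 and PDK4 (glucose). Further ones are KLF9, CEBPB and CEBPD (KLF and C/EBP), PER1 (clock), FOXO1 and FOXO3 (autophagy), GADD45A and GADD45B (cell cycle control) and FKBP5 (heat shock). The median and mean log2 fold change differed in sign for the cell cycle control list (-0.04 and 0.45), the heat shock list (-0.02 and 0.27) and the markers of other cell types (0.17 and -0.09), and camera pointed up for each. For the immediate-early list both were negative (-0.16 and -0.10) while camera and fry pointed up. NR1D2, CSNK1D, JUNB, SLC26A2, SCNN1A, BCL2L11, TXNRD1, ETV5, SQSTM1, DNAJB1, SOCS1, HSP90B1 and GAPDH also overlap other tested genes, so the assignment of part of their reads is uncertain.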

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

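The recalculation without transcripts that hold a long run of A or T was chosen only after the result was seen. The share of aligned reads on transcripts that did not stand for their gene, which the gene tests do not use, was higher in both dex libraries than in either etoh library, at 46.6% ± 0.383 (SD, n = 2) in dex and 45.7% ± 0.373 (SD, n = 2) in etoh. Without those transcripts the shares were 47.7% ± 0.193 in dex and 47.3% ± 0.0801 in etoh.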

How the results depend on the processing

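Removal of transcripts with a run of at least 30 A or T was chosen only after results were seen, and it gave 1320 called genes, 824 higher and 496 lower. The main counts of 1300 called, 815 higher and 485 lower moved by over 1.5 times with DESeq2 and at an adjusted p of 0.01. DESeq2 called 715, 456 higher and 259 lower, and the stricter threshold left 836, 537 higher and 299 lower. The called and lower counts also moved by over 1.5 times without etoh replicate 1. The number of genes changed at least 2-fold, 463 in the main test, moved by less in each of these settings. The cause of the lower DESeq2 count was not tested, although DESeq2 also recovered fewer of the changed genes in data simulated with edgeR's dispersions. All 715 DESeq2 calls were among the 1300. Leaving out 1 library at a time gave 848 to 1493 called genes, 544 to 866 higher, 304 to 627 lower and 414 to 502 changed at least 2-fold, from fewer libraries. Other normalization, filter, dispersion, limma-voom and mitochondrial settings gave 1255 to 1403 called genes, and the sum of all transcripts gave 1684, of which 1228 were shared with the main calls. Higher genes made up 62.7% of calls, and 56.1% with library totals alone, the lowest share of any setting. Genes called both in the main test and in any of these settings had the same direction in both. With the replicate number as a block 1118 genes were called, 1115 of them shared with the main calls, and with 2 numbers whose deviations correlated at -0.0796 across genes nothing shows that the numbers pair the samples. Of 126 called genes among the 143 chosen, 111 passed in every setting that tested them, the 0.01 threshold aside, 15 did not pass in at least 1, and 0 reversed. DESeq2 did not call 8 of them, among them RARA, INSIG1, RPL3, BCL2A1, RPL27, VEGFA and PRRG3, and the block ended the calls of ACTB and PRRG3. With the block 5 NRF2 responsive genes were lower and 1 higher, 1 gene was lower in each of the glucose and heat shock lists, and 0 reference genes were called. COL1A1 and KLF15, not called in the main test, passed in at least 1 setting. At this depth, with 2 libraries per group, edgeR recovered 43.3% of simulated 1.5-fold changes in genes above 2 CPM. That simulation used edgeR's own dispersions and 200 changed genes, and depth was not varied.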

Other observations

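Among the tests here, expression of PRRG3 and poly(A) reads were put to the test only after their results were seen. The 3' UTR annotation, the sequence threshold for neighbouring genes, the division of neighbours by orientation and the restriction of the run search to transcripts of the deposited length were also chosen after first results. The first sequence threshold for neighbours was 97% identity over 100 bases. A search of every pair of neighbours for shared sequence, called or not, was added later still. The restriction left out 12 transcripts whose reference sequence has another length and a run of at least 40 A or T, with between 0 and 19975 reads, DNMT3A with a run of 52 and 160 reads among them.

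Some long noncoding RNAs also changed. Of 1484 tested long noncoding genes, 62 rose and 29 fell (6.13%), against 729 and 439 of 11839 protein-coding genes (9.87%), a difference in shares that was not tested. LUCAT1, a stress-responsive noncoding RNA, went from 7.25 ± 1.32 to 2.03 ± 0.814 CPM (log2 fold change -1.82, SE 0.28). MIR503HG, the host transcript of a microRNA cluster, rose from 3.26 ± 0.296 to 8.46 ± 0.528 CPM (1.36, SE 0.23). PXN-AS1 rose by 0.90 (SE 0.13) and SLC7A11-AS1 fell by 0.94 (SE 0.17), but each overlaps a coding gene on the other strand, PXN and SLC7A11, and the counts cannot separate them. All 4 passed in the main test and in every setting tried on single genes.

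Among genes for factors of mRNA decay, besides ZFP36, the endonuclease gene ZC3H12A rose from 10.4 ± 1.31 to 33.1 ± 5.12 CPM (1.67, SE 0.15) and ZFP36L2 from 61.1 ± 6.25 to 93.7 ± 2.38 CPM (0.62, SE 0.12). Next to EREG on chromosome 4, the related ligand AREG went from 12.4 ± 0.595 to 3.51 ± 0.769 CPM (-1.83, SE 0.21). These genes were singled out after their values were seen, and neither group was tested as a list.

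Genes lower in dex held AU-rich nonamers, the sites of decay factors such as ZFP36, in their 3' UTRs more often than other genes: 160 of 426 (37.6%), with IL11, PTGS2 and CXCL1 among them. Random sets of 426 uncalled genes gave a median of 20.9%. Sets matched on 3' UTR length and CPM gave a median of 27.5% with a 95% range up to 31.2%. Sets matched on AU content as well gave a median of 29.8% with a range up to 33.8%. The permutation p was 0.0001 each, one-sided, the smallest that 10000 sets can give. Length, level and AU content may thus account for part of the excess. Matching used 5 classes of length, 5 of CPM and 3 of AU content. Lower genes had a median 3' UTR of 1980.5 bases and 63.2% AU, against 1329 bases and 58.3% in uncalled genes. Differences within classes may remain, so whether these features account for all of the excess cannot be told. Genes higher in dex also held nonamers more often than their fully matched sets, 25.7% against a range of 17.8 to 23.2%, although within the range of sets matched on length and CPM alone (20.2 to 25.9%), so the nonamer may mark regulated transcripts of either direction. Neither mRNA decay nor transcription was measured here. A first version with another 3' UTR annotation covered fewer than 80% of genes in some classes and was replaced after its result was seen.

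Genes next to each other were higher together more often than when calls were shuffled among genes of similar CPM. The shuffles did not match base composition or gene density, which neighbours may share, so these were not tested as a source. The median AU content of 3' UTRs was 53.5% in higher, 63.2% in lower and 58.3% in uncalled genes. Of 7233 adjacent pairs within 100 kb that did not overlap, with shared sequence searched from called genes only, 71 were both higher, against a permuted median of 26 and a 95% range of 17 to 36 (permutation p = 0.0001, one-sided, the smallest possible here). Of 6597 pairs in which both genes were searched and shared no sequence at 90% identity over 50 bases, 68 were both higher, against a range of 15 to 34. Overlap or such sequence between the genes of a pair thus does not account for the excess. CDH16 with RRAD on chromosome 16, WISP1 with NDRG1 on chromosome 8 and FKBP5 with ARMC12 on chromosome 6 were among these pairs, chosen after their values were seen. Pairs whose genes both overlap another called gene stayed in, such as RP11-158M2.2 with RP11-158M2.3, which both overlap AKAP13. Among coding genes alone, 57 of 6161 such pairs were both higher, against a range of 15 to 34. Pairs both lower numbered 19 of the 7233, against a permuted range of 4 to 16 (permutation p = 0.0031, one-sided), and 18 of the 6597, against 3 to 14. Shared regulation of neighbours may explain this, but transcription running on from an induced gene stays open, since coding pairs pointing away from each other, which run-on cannot join, were both higher in 12 cases, within a permuted range of 2 to 12 over all such pairs but past a range of 2 to 11 over those searched (permutation p = 0.028 and 0.0169, one-sided). The other orientations lay further past their ranges. Over all such pairs, coding genes on the same strand were both higher in 32 cases, against a range of 7 to 22. Coding genes pointing at each other were both higher in 16, against 2 to 11 (permutation p = 0.0001 and 0.0004, one-sided).

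PRRG3, a gene for a membrane protein, held 1.56% and 2.06% of aligned reads in dex and 3.10% and 2.00% in etoh, 923670 reads in all. Its counted transcript shared no stretch of at least 50 bases at 95% identity with the mitochondrial ribosomal RNAs. That argues against reads from such a stretch, and shorter or less similar matches were not searched. Its 4 other transcripts held 0% of its reads although they share sequence with it, which argues against expression of the gene. The transcript holds a run of 56 T in its 3' UTR, the longest run of A or T among 100607 transcripts searched, and the ratio to PRRG3 of the 10 most-read other transcripts with a run of at least 40 differed between libraries by 1.04-fold for AC009501.4 to 1.36-fold for TPH1, so reads of poly(A) tails are a candidate explanation. PRRG3 was called lower in dex (-0.46, SE 0.15, adjusted p = 0.044 by edgeR), but not with DESeq2 (-0.47), without etoh replicate 1 (-0.10), without dex replicate 1 (-0.29) or in 4 other settings. Of 93 tested genes with a run of at least 30 A or T, PRRG3 included, 13 were lower and 3 higher, with TPH1 at -0.53, MED28 at -0.45 and SLC25A37 at -0.61 among the lower (named after their values were seen), so part of these calls may rest on the same reads.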
